A study of Mus musculus with 61 samples.

How the data were processed

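The series holds 61 samples of a mouse CD8-positive dendritic cell line that the labels describe as dendritic cells from the spleen. Of these, 21 are RNA sequencing libraries, 38 are chromatin immunoprecipitation (ChIP) samples against 12 factors and 2 are ATAC samples. The ChIP and ATAC samples were not analysed here, because the processed table holds gene values of the RNA libraries only. Per the labels' protocols, cells were left unstimulated or were given poly(I:C) of high molecular weight (pIC), a class B CpG oligonucleotide (CpG) at 1 mM, or interferon beta (IFNb) at 10 U. The pIC dose is 5 μg/ml in the labels' treatment protocol and 5 mg/ml in the labels' sample characteristics. The treatment protocol names the 90 min time alone, and the 6 h time comes from the sample titles and characteristics. Each of the 7 groups (unstimulated, and pIC, CpG and IFNb at 90 min and at 6 h) has 3 libraries numbered 1 to 3. The labels do not say whether these numbers mark separate cultures, so every p-value measures the spread between these samples. No unstimulated library was taken at 6 h.

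Per the labels' protocols, RNA libraries were prepared from total RNA with an Ultra II RNA kit, and the series used Illumina sequencers of more than one model; the labels do not say which library ran on which. Per the submitters' processing notes, HISAT2 2.1.0 and Picard 2.8.1 were among the tools and mm10 was the genome build. The counting tool, the annotation, the strand setting and the scaling are not given in the sources used here. Genes that share reads with near-identical copies (such as Tgtp1 and Tgtp2, Ifit3 and Ifit3b, Hba-a1 and Hba-a2, the Gbp, Ifi200 and interferon lambda families, and MHC class I genes) are therefore uncertain as single genes.

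The deposited values are on a log2 scale, centred by gene: the median over the 21 libraries was 0 for each of the 38087 genes, so the level of one gene cannot be set against that of another. Of these genes, 12907 had one value in all libraries. Low values fell on a common floor per gene, and their steps matched reads scaled per library and floored at 1 scaled unit before the logarithm; 59.6% of the 58157 low values checked were whole reads within 0.02 reads, so the reads themselves were not recovered. What one read was worth served as the measure of depth. It ranged from 0.641 scaled units in unstimulated replicate 2 to 2.93 in pIC 90 min replicate 2, a 4.57-fold range of depth, and the next shallowest library was CpG 6 h replicate 3 at 1.68. The total reads of each library are unknown. The library medians of genes above the floor were 0 in every library, so the deposited values were used without further scaling. With these medians equal, a change common to most genes could not be seen. The balance of higher and lower calls in each comparison depends on this scaling. Of the 38087 gene identifiers (Ensembl), 36308 were matched to a symbol in the supplied table of gene names, and 20093 of the tested ones were.

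The design written before the data were examined assumed counts and had a separate branch for values already on a log scale. That branch was used. A gene was tested when it lay above its own lowest value in at least 3 libraries, which left 20507 genes; for 6405 of them at least 2 libraries shared the lowest value, and this is called the floor. All 21 libraries entered one fit in limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with one coefficient per group and empirical Bayes moderation with the trend and robust options. Each of the 15 comparisons was two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Errors after ± are the standard errors of that fit unless SD is written, with n = 3 libraries per group. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. A fold against a group with every library at the floor is a lower bound, computed with 3 reads per library in place of the floor.

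The lists of genes were written before the data were examined, and 31 lists with at least 5 tested members were tested in each comparison with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The list of mitochondrial transcripts had no member in the table. The estimated correlation of camera was the alternative. Where both are given below, the p-values at the preset correlation were the smaller ones. Their size can overstate the certainty for lists whose genes vary together. The lists hold 647 tested genes, 37 of them in more than 1 list. Counts of members called are given over all genes tested and adjusted over the list alone. In addition, 25 genes formed a panel, each of them a member of another list too. For the panel, the difference between a pair of stimuli in the change from 90 min to 6 h was tested in the same fit, adjusted over the 25 genes and the 3 pairs. Markers of 11 other tissues were listed after the values had been seen but before their own test.

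Genes named in the text follow a rule set before the data were examined. In comparisons with unstimulated cells these are the 10 called genes with the highest and the 5 with the lowest log2 fold change, provided that all 3 libraries of one group lay beyond all 3 of the other and that the mean value of the higher group lay above the median of the tested genes. In the other comparisons 5 each way were taken. The panel genes were added throughout, and from each list up to 4 called members of largest change, or those of highest mean where none was called. Predicted and unnamed genes were counted but not named. The means in these rules are of values centred by gene, so they do not select genes of high expression. The trend option of limma rests on such means too. Beside 3 libraries against 3, 10% of genes have groups that do not overlap by chance.

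The procedure was tested on simulated data with the fitted spread of each gene. In these data all 21 libraries had the same spread, genes were independent and no floor was set, unlike in the real libraries. The shares below therefore hold for that setting alone. In a simulation of pIC 90 min against unstimulated with 20507 genes, 200 of them changed, it recovered 10.4% of changes of log2 0.5, 53.7% of changes of 1 and 81.8% of changes of 2; among genes without a seen floor these shares were 15.9%, 62.7% and 90.0%. Of the 100 genes it called, 3 were false and 0 of the recovered ones had the wrong sign.

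The alternatives chosen before the data were examined were quantile normalization, limma without the trend and robust options, no filter on low values (25180 genes), a stricter filter (at least 5 scaled units in at least 3 libraries for genes with a seen floor, 15462 genes), the 2 compared groups fitted alone, the replicate number as a block, camera's estimated correlation, and each of the 21 libraries left out in turn. Another pseudocount was not run, because the values were deposited as log2. Quantile normalization acted on values already centred by gene, so it gave every library the same distribution of differences from the gene medians. It can shrink real changes in some libraries and stretch them in others. Its values therefore do not show how another scaling of the reads would act. Library quality weights, a fit without 3 doubted libraries (replicate 2 of the unstimulated, pIC 90 min and IFNb 90 min groups, with the lowest quality weights of all, 0.39, 0.41 and 0.14), and the replicate block with the 2 compared groups alone were chosen after the data had been seen. To check whether the replicate numbers pair the samples, the deviations from the group means of same-numbered libraries were correlated across genes without a seen floor. All 3 correlations were over 0.1 in 1 comparison, IFNb 90 min against unstimulated (0.16, 0.39 and 0.22 for numbers 1, 2 and 3). Blocked values stand beside that result. Comparisons against unstimulated cells share the same 3 libraries, so their overlap was set beside that of independent lists, and the covariance and correlation of their log2 fold changes beside 20 simulations of unchanged groups.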

Results

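RNA sequencing of a mouse CD8-positive dendritic cell line gave 21 libraries in 7 groups of 3. The groups were unstimulated cells and cells given poly(I:C) (pIC, double-stranded RNA), a class B CpG oligonucleotide (CpG, a ligand of TLR9) or interferon beta (IFNb) for 90 min or 6 h. The table gives log2 values centred on the median of each gene, so it shows differences between libraries and no levels. The depth of the libraries ranged 4.57-fold: one read was worth 0.641 scaled units in unstimulated replicate 2 and 2.93 in pIC 90 min replicate 2, the shallowest library. Across genes, the lowest correlations between replicates were 0.45 in the IFNb 90 min group and 0.46 in the pIC 90 min group. With values centred by gene, these correlations also depend on how far a group lies from the gene medians. At 90 min the median SD over genes was 0.222 with IFNb, 0.126 with pIC and 0.126 with CpG, against 0.150 in unstimulated cells. At 6 h it was 0.081 with IFNb, 0.081 with pIC and 0.117 with CpG. The first principal component held 35.3% of the variance and the second 22.1%. Of 38087 genes, 20507 were tested. The first set of comparisons asked which genes each stimulus changed at each time.

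After 90 min of pIC, 4252 genes were called against unstimulated cells, 2331 higher and 1921 lower, and 1094 and 359 of them changed at least 2-fold. Of the 6405 genes with a seen floor, 2135 and 2368 were at it in pIC 90 min replicates 1 and 3. Every other library had 3084 or more, among them pIC 90 min replicate 2 with 3726. How far this adds to the genes called higher with pIC at 90 min was not tested. Acod1 (ENSMUSG00000022126), which encodes the itaconate-forming enzyme of activated myeloid cells, rose by 10.12 ± 0.27 on the log2 scale (adjusted p = 2.12e-13, n = 3 in each group). Il12b (ENSMUSG00000004296), a subunit of the cytokines that drive T helper responses, rose by 8.87 ± 0.23 and Tnf (ENSMUSG00000024401) by 8.19 ± 0.18. The chemokine genes Ccl5 and Cxcl10 rose by 7.83 ± 0.27 and 7.17 ± 0.16, and the co-stimulatory receptor gene Cd40 by 4.31 ± 0.10. Interferon genes rose too: Ifnb1 by 8.08 ± 0.35, with 2 of 3 unstimulated libraries at the floor, while Ifnl2 was at least 12.5-fold and Ifnl3 at least 9.53-fold higher than in unstimulated libraries that were all at the floor. The RNA sensor gene Ifih1 rose by 4.06 ± 0.15.

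Gbp2b rose by 5.27 ± 0.35, Ifit1 by 4.46 ± 0.49 with 2 of 3 unstimulated libraries at the floor, Isg15 by 3.77 ± 0.21 and Oasl1 by 3.12 ± 0.12, while Stat1 did not pass (-0.04 ± 0.11, adjusted p = 0.856) and Stat2 fell by 0.60 ± 0.11, a call that ended when the 2 groups were fitted alone (adjusted p = 0.0723). Quantile normalization turned the rises of Usp18 (0.54 ± 0.13) and Mx1 (0.63 ± 0.16) to -0.70 and -0.35 and made Stat1 a call at -0.61. Irf8, a transcription factor that keeps the identity of these cells, fell by 1.71 ± 0.09. The largest falls were in Rab3a (-3.92 ± 0.29), Cbx8 (-3.59 ± 0.17), the Notch target Hes1 (-3.27 ± 0.27) and the Wnt receptor gene Fzd10 (-3.15 ± 0.14); quantile normalization made the falls of Hes1 and Fzd10 larger, at -6.59 and -5.70.

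Of 31 gene lists, 13 were called in camera, all upwards. Of 32 NF-κB pathway genes, 31 rose (32 adjusted over the list alone), with a median log2 fold change of 2.94 (camera adjusted p = 1.1e-52). Of 22 chemokine genes 15 rose (17 adjusted over the list alone, adjusted p = 1.04e-15), and of 31 genes of dendritic cell maturation 19 rose and 1 fell (20 and 1 adjusted over the list alone, 1.3e-16). Of 64 antiviral effector genes, 31 rose, 2 fell and 31 did not pass (33 and 4 adjusted over the list alone), with a median of 0.38 (5.07e-08). Inflammatory cytokines, interferon genes, negative regulators, MHC class I presentation, immediate early genes, cell death genes and genes of the unfolded protein response were the other lists that held with an estimated correlation. Nucleic acid sensors (0.0624 with an estimated correlation) and interferon-induced GTPases (0.44) lost their call. With the 2 groups fitted alone 2611 genes were called. Quantile normalization moved the share of higher calls from 54.8% to 40.6%.

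After 90 min of CpG, 5106 genes were called against unstimulated cells, 2551 higher and 2555 lower, 943 and 635 of them at least 2-fold. Il12b rose by 11.29 ± 0.23 (adjusted p = 4.75e-15), Tnf by 9.13 ± 0.18 and Il1b, the precursor of a cytokine of fever and neutrophil recruitment, by 8.39 ± 0.46. Cxcl2, a neutrophil chemokine gene, rose by 8.13 ± 0.36, Ccl17 by 7.38 ± 0.34, and Ier3, an immediate early gene of survival, by 7.80 ± 0.29. Cd40 rose by 4.90 ± 0.10 and Socs3, a feedback inhibitor of cytokine receptors, by 4.90 ± 0.13. Ifnb1 rose by 5.47 ± 0.35, with 2 of 3 unstimulated libraries at the floor. Irf8 fell by 2.18 ± 0.09, Stat2 by 0.95 ± 0.11 and Cbx8 by 3.82 ± 0.17. Among effectors of the interferon response, Slfn2 rose by 2.97 ± 0.07 and Rsad2 did not pass (0.06 ± 0.37, adjusted p = 1.00). The rise of Isg15 (0.72 ± 0.21) ended with quantile normalization (-0.05), with the 2 groups alone, and without unstimulated replicate 1 (0.63), unstimulated replicate 3 (0.49) or CpG 90 min replicate 3 (0.63). Ifit1 did not pass (1.14 ± 0.49) but was called at 2.03 without unstimulated replicate 2.

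All 12 lists called moved upwards. All 32 NF-κB pathway genes rose, with a median of 3.31 (camera adjusted p = 1.42e-51), as did 17 of 22 chemokine genes (17 adjusted over the list alone, 1.16e-14) and 21 of 31 maturation genes, of which 1 fell (24 and 1 adjusted over the list alone, 4.18e-19). With chemokine genes at their bounds the median of that list was 2.49 in place of 3.11. Inflammatory cytokines, negative regulators, MHC class I presentation, immediate early genes, the unfolded protein response and cell death genes, whose median was 0.00 and mean 0.72, held with an estimated correlation. Antiviral effectors, with 19 up, 5 down and 40 not passing (21 and 7 adjusted over the list alone, adjusted p = 0.0176), lost their call at 0.461, nucleic acid sensors at 0.177 and stable reference genes, with 9 up and 1 down, at 0.5.

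After 90 min of IFNb, 2826 genes were called against unstimulated cells, 1522 higher and 1304 lower, 743 and 121 of them at least 2-fold. Iigp1 (ENSMUSG00000054072), a GTPase that attacks the vacuoles of parasites, rose by 8.37 ± 0.80 and Ifit1 by 7.10 ± 0.49, each with 2 of 3 unstimulated libraries at the floor. Isg15, a ubiquitin-like modifier, rose by 5.02 ± 0.21 (adjusted p = 4.74e-11), Mx1 by 3.88 ± 0.16 and Oasl1 by 3.09 ± 0.12. The signalling genes Stat1, Stat2 and Irf9 rose by 2.38 ± 0.11, 2.79 ± 0.11 and 2.05 ± 0.08, and the feedback inhibitor genes Socs1 and Usp18 by 4.98 ± 0.27 and 4.11 ± 0.13. Cd40 rose by 3.04 ± 0.10, Tap1 by 1.26 ± 0.10 and Cdkn1a, a brake of the cell cycle, by 2.44 ± 0.11. Cxcl11 was at least 10.4-fold higher than in unstimulated libraries that were all at the floor. Ifnb1 (0.19 ± 0.35), Il12b (0.41 ± 0.23) and Irf8 (0.05 ± 0.09) did not pass. Quantile normalization turned the rise of Tnf (0.91 ± 0.18) to -0.47. The largest fall was in Fzd10, at -2.65 ± 0.14, which quantile normalization put at -5.06.

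Of 64 antiviral effector genes, 63 rose (64 adjusted over the list alone), with a median of 2.78 (2.67 with genes at their bounds, camera adjusted p = 2.76e-94). All 21 interferon-induced GTPases rose, with a median of 5.28 (2.09e-41), and 17 of 29 nucleic acid sensors, of which 1 fell (19 and 2 adjusted over the list alone, 4.42e-26). NF-κB pathway genes shifted upwards by a median of 0.47, with 15 of 32 called (19 adjusted over the list alone, 7.95e-10). STAT and IRF regulators, negative regulators, cytokines, chemokines, maturation, MHC class I presentation, cell death and the factors of the ChIP samples also moved upwards, and cell cycle genes moved down, with 8 lower and 3 higher of 40 (3 up and 14 down adjusted over the list alone, 0.000453). Of 19 lists called, 6 lost their call with an estimated correlation: cholesterol synthesis (0.557) and the unfolded protein response (0.0646), both down, and oxidative phosphorylation (0.814), plasmacytoid dendritic cell markers (0.0662), macrophage markers (0.643) and T and NK cell markers (0.0662), all up.

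In this comparison alone, all correlations between same-numbered libraries were over 0.1, which does not show that the numbers pair the samples. On average, 13 of the 21 libraries correlated best with libraries of their own number in other groups. With 3 numbers to choose from, this is more than an even choice would give. The numbers may therefore hold structure in other comparisons too. Replicate 2 was the highest of its group for haemoglobin and collagen transcripts in both groups compared. Pairing cannot be told apart from that. With the replicate block and the 2 groups alone, 450 genes were called, against 1093 without the block. Of 98 named genes called, 34 kept their call, among them Stat1, Stat2, Isg15, Mx1, Oasl1, Irf9, Socs1, Usp18, Cd40, Tap1, Cdkn1a and Fzd10, and 64 lost it, among them Iigp1 (adjusted p = 0.111), Ifit1 (0.0878) and Tnf (0.191). In the blocked camera test antiviral effectors (2.23e-38), GTPases (4.67e-16), cell cycle (0.000155) and oxidative phosphorylation (0.000179) held. Cholesterol synthesis (0.018), the unfolded protein response (0.0163) and plasmacytoid dendritic cell markers (0.00335) held too. Macrophage markers (0.206) and T and NK cell markers (0.162) lost their call, and ribosomal proteins gained a call (0.0027). Quantile normalization moved the share of higher calls from 53.9% to 41.2%. IFNb 90 min replicate 2 had the lowest quality weight of all libraries (0.14). Of 357 genes that IFNb induced at least 4-fold in the other replicates, 248 were induced less in it. That choice of genes itself favours a lower value in the left-out library. Isg15, Socs1 and Oasl1 had their highest value of the 3 replicates in replicate 2.

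**Figure D1:**
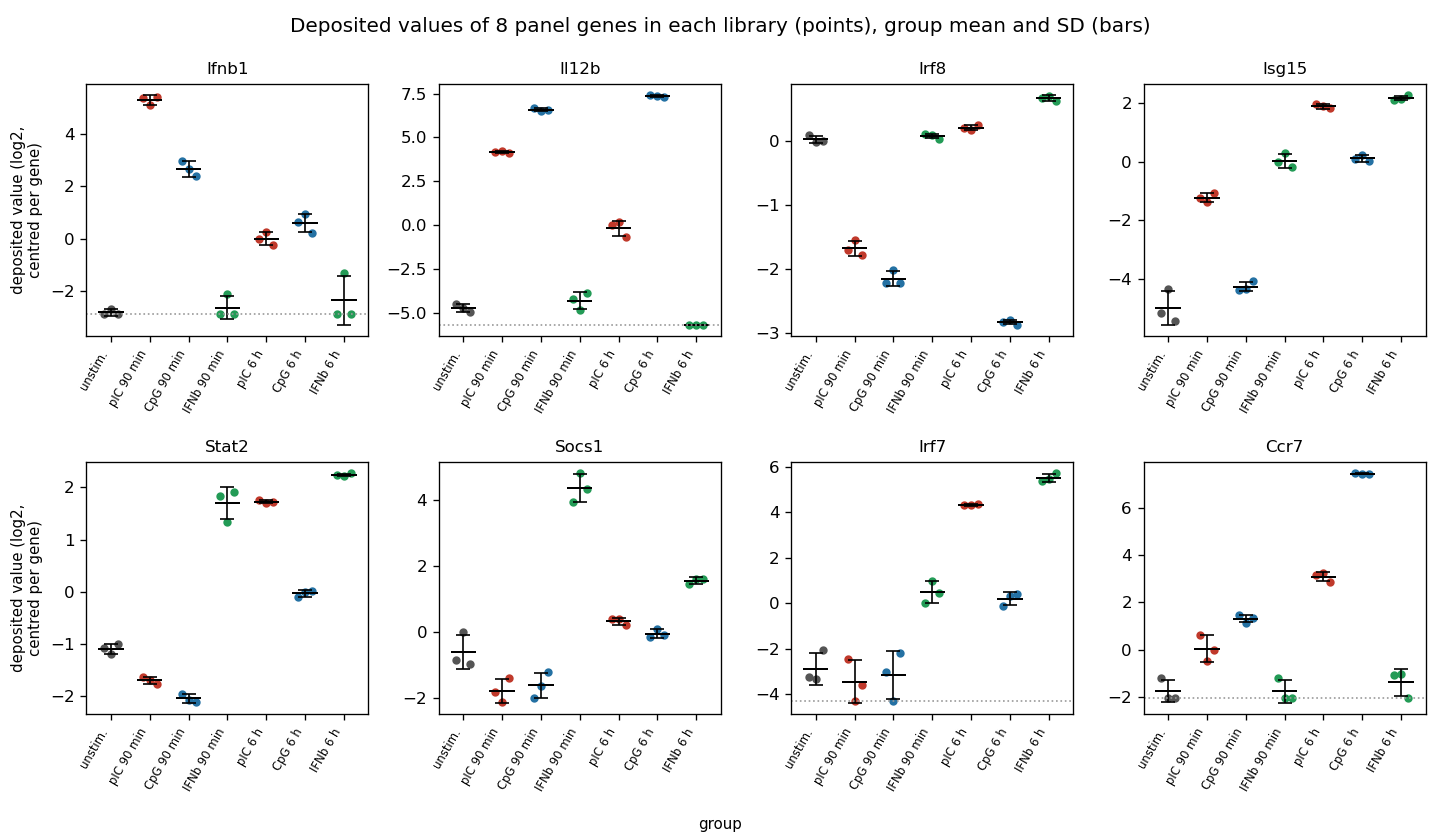
Deposited log2 values, centred per gene, of 8 panel genes in each of the 21 libraries (points), with the mean and SD of each group of 3 (bars) and the floor as a dotted line where at least 2 libraries share it. Ifnb1 was highest with pIC at 90 min, Il12b with CpG at 6 h, and Socs1 with IFNb at 90 min.

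The 6 h groups were compared with the same unstimulated libraries, so these differences hold the time in culture as well as the stimulus. Transcripts that the cell line would not need differed between the 2 sets of libraries. Above its lowest value, Hba-a1 averaged 5.33 on the log2 scale in unstimulated libraries, 5.02 in the 9 libraries of 90 min and 0.14 in the 9 of 6 h, and Col1a1 averaged 4.05, 3.95 and 0.32. Hbb-bs, Hbb-bt and Col3a1 went the same way, and of the 12 earlier libraries 0 were at the floor for any of these genes.

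**Figure D2:**
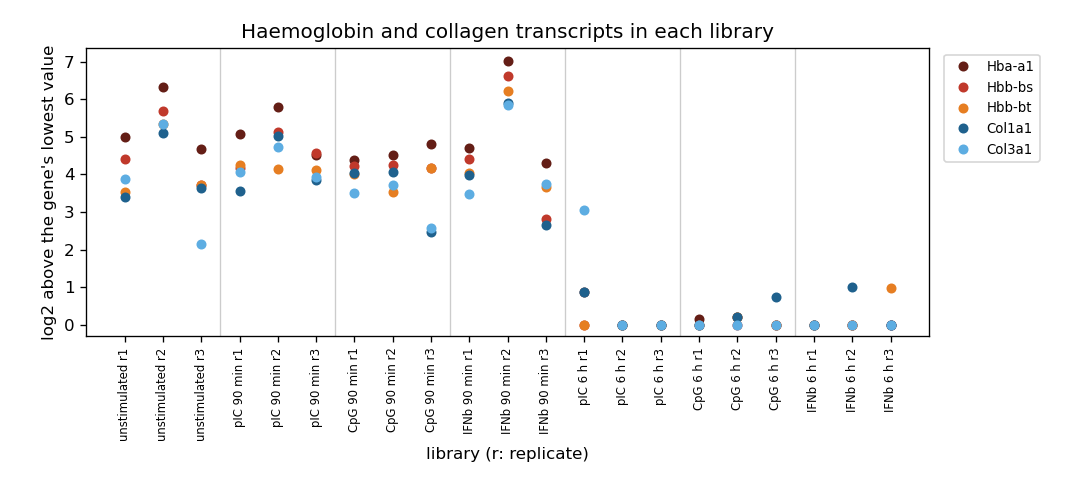
Log2 value above the lowest value of each gene for 3 haemoglobin and 2 collagen transcripts in each of the 21 libraries, with r for replicate. Hba-a1 averaged 5.33 in the unstimulated and 0.14 in the 6 h libraries, and IFNb 90 min replicate 2 had the highest values of each transcript.

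After 6 h of pIC, 9567 genes were called against unstimulated cells, 4958 higher and 4609 lower, 2379 and 1469 of them at least 2-fold. Acod1 rose by 10.21 ± 0.27 (adjusted p = 7.13e-14) and Ccl5, a chemokine gene for effector T cells, by 10.09 ± 0.27. Ifit1, whose product binds viral RNA, rose by 9.72 ± 0.49 with 2 of 3 unstimulated libraries at the floor, and the GTPase genes Gbp2b and Gbp2 rose by 9.66 ± 0.35 and 8.66 ± 0.20. Irf7, which amplifies interferon production, rose by 7.21 ± 0.50, Ddx58 by 7.59 ± 0.23, Isg15 by 6.88 ± 0.21 and Stat1 by 4.26 ± 0.11. Cxcl13 was at least 54.9-fold higher than in unstimulated libraries at the floor. Il12b (4.54 ± 0.23), Tnf (3.91 ± 0.18) and Ifnb1 (2.81 ± 0.35, with 2 of 3 unstimulated libraries at the floor) rose as well. Irf8 (0.18 ± 0.09) and Irf1 (0.16 ± 0.12) did not pass; Irf1 was called at 0.29 without unstimulated replicate 2. Chac1, a gene of the amino acid stress response, fell by 5.66 ± 0.20 and Gpnmb, a lysosomal glycoprotein gene, fell by 6.09 ± 0.65.

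All 64 antiviral effector genes rose, with a median of 3.99 (camera adjusted p = 8.73e-48), as did 20 of 21 interferon-induced GTPases (21 adjusted over the list alone, median 6.52, 6.31e-18) and 23 of 29 nucleic acid sensors, of which 4 fell (23 and 5 adjusted over the list alone, 7.63e-11). NF-κB pathway genes (26 up and 1 down of 32, 2.99e-15), maturation genes (23 up and 1 down of 31, 24 and 1 adjusted over the list alone, 1.47e-10) and MHC class I presentation (21 up and 2 down of 26, 22 and 2 adjusted over the list alone, 6.18e-08) also moved upwards. STAT and IRF regulators, cytokines, chemokines and cell death genes moved upwards and held with an estimated correlation, and cell cycle genes moved down (24 lower and 9 higher of 40, 0.000813). Of 16 lists called, 5 lost their call with an estimated correlation: immediate early genes, with 20 of 33 lower and 7 higher (0.2), and glycolysis, with 13 of 20 lower and 2 higher (0.0783), both down, and cDC1 identity (0.2), negative regulators (0.312) and the factors of the ChIP samples (0.0783), all up. Quantile normalization moved the share of higher calls from 51.8% to 47.1%.

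After 6 h of CpG, 10060 genes were called against unstimulated cells, 5180 higher and 4880 lower, 2477 and 2198 of them at least 2-fold. Il12b rose by 12.06 ± 0.23 (adjusted p = 1.72e-15), the chemokine genes Ccl3 and Ccl4 by 10.96 ± 0.22 and 10.96 ± 0.30, Il1b by 10.70 ± 0.46 and Il6, a cytokine gene of acute inflammation, by 9.72 ± 0.18. Ccr7, the receptor that guides dendritic cells to lymph nodes, rose by 9.20 ± 0.34 with 2 of 3 unstimulated libraries at the floor. Lad1 was at least 436-fold higher than in unstimulated libraries at the floor. Isg15 rose by 5.11 ± 0.21, Usp18 by 4.70 ± 0.13, Stat1 by 3.01 ± 0.11 and Irf7 by 3.09 ± 0.50. Irf8 (-2.86 ± 0.09) and the parasite sensor genes Tlr12 (-3.63 ± 0.08) and Tlr11 (-3.10 ± 0.12) fell, while Xcr1 rose by 2.73 ± 0.07. The class II loading genes H2-DMa and H2-DMb1 fell by 3.73 ± 0.16 and 3.21 ± 0.14. Irf1 fell by 1.53 ± 0.12 (-0.98 with quantile normalization), Acss1, which makes acetyl-CoA from acetate, fell by 7.25 ± 0.31, and the chemokine receptor gene Cxcr3 fell by 7.14 ± 0.47.

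Antiviral effectors rose in 59 of 64 and fell in 1 (59 and 2 adjusted over the list alone), with a median of 2.77 at their bounds (camera adjusted p = 1.3e-28). NF-κB pathway genes rose in 30 of 32 and fell in 1 (7.55e-21), maturation genes in 23 of 31 with 2 falling (2.2e-09), chemokines in 18 of 22 with 2 falling (5.21e-08), and GTPases in 18 of 21 (9.44e-11). Cytokines, negative regulators and nucleic acid sensors also moved upwards. MHC class II presentation moved down, with 13 of 17 lower and 1 higher (3.09e-05, 0.038 with an estimated correlation), and so did glycolysis, with 15 of 20 lower (1.17e-06, 0.048 with an estimated correlation). The list of cDC1 identity, with 18 of 32 lower and 9 higher (9 up and 19 down adjusted over the list alone, 0.00252), was the 1 of 11 called lists that lost its call with an estimated correlation (0.151). Quantile normalization moved the share of higher calls from 51.5% to 48.6%.

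After 6 h of IFNb, 8985 genes were called against unstimulated cells, 4545 higher and 4440 lower, 2047 and 1301 of them at least 2-fold. Ifi213, a gene of the family of interferon-inducible DNA sensors, rose by 9.69 ± 0.50 (adjusted p = 2.48e-10), Slfn5 by 9.03 ± 0.30, Irf7 by 8.40 ± 0.50, Isg15 by 7.16 ± 0.21 and Usp18 by 5.76 ± 0.13. Stat1 and Stat2 rose by 4.52 ± 0.11 and 3.33 ± 0.11. Irf8 rose by 0.64 ± 0.09, and Xcr1 and Tlr3, a receptor for double-stranded RNA, by 2.12 ± 0.07 and 2.09 ± 0.15. Cd40 rose by 1.79 ± 0.10 and Cxcl10 by 3.90 ± 0.16. Ifnb1 (0.46 ± 0.35) and Tnf (0.10 ± 0.18) did not pass, and quantile normalization put Tnf at -0.66 with a call. Il12b fell by 0.95 ± 0.23, with 2 of 3 IFNb libraries at the floor and the third just above it (-2.09 with quantile normalization). Junb fell by 1.36 ± 0.11 and the immediate early gene Egr3 by 4.57 ± 0.21. Chac1 fell by 5.41 ± 0.20 and Gpnmb by 6.23 ± 0.65.

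Of 64 antiviral effector genes 63 rose, with a median of 4.28 (camera adjusted p = 9.54e-53), and all 21 GTPases rose, with a median of 6.65 (3.41e-20). Nucleic acid sensors (21 up and 2 down of 29, 9.6e-14), STAT and IRF regulators (11 up and 1 down of 17, 3.5e-05), cDC1 identity (20 up and 2 down of 32, 22 and 2 adjusted over the list alone, 1.13e-06) and inflammatory cytokines, with a median of 0.10 and a mean of 1.24 (0.00747), moved upwards. Of 11 lists called, 5 lost their call with an estimated correlation: immediate early genes, with 23 of 33 lower and 4 higher (0.0636), cholesterol synthesis, with 20 of 24 lower and 1 higher (0.26), and cell cycle genes (0.137), all down, and MHC class I presentation (0.0552) and maturation genes (0.0636), both up. Quantile normalization moved the share of higher calls from 50.6% to 47.8%.

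**Figure D3:**
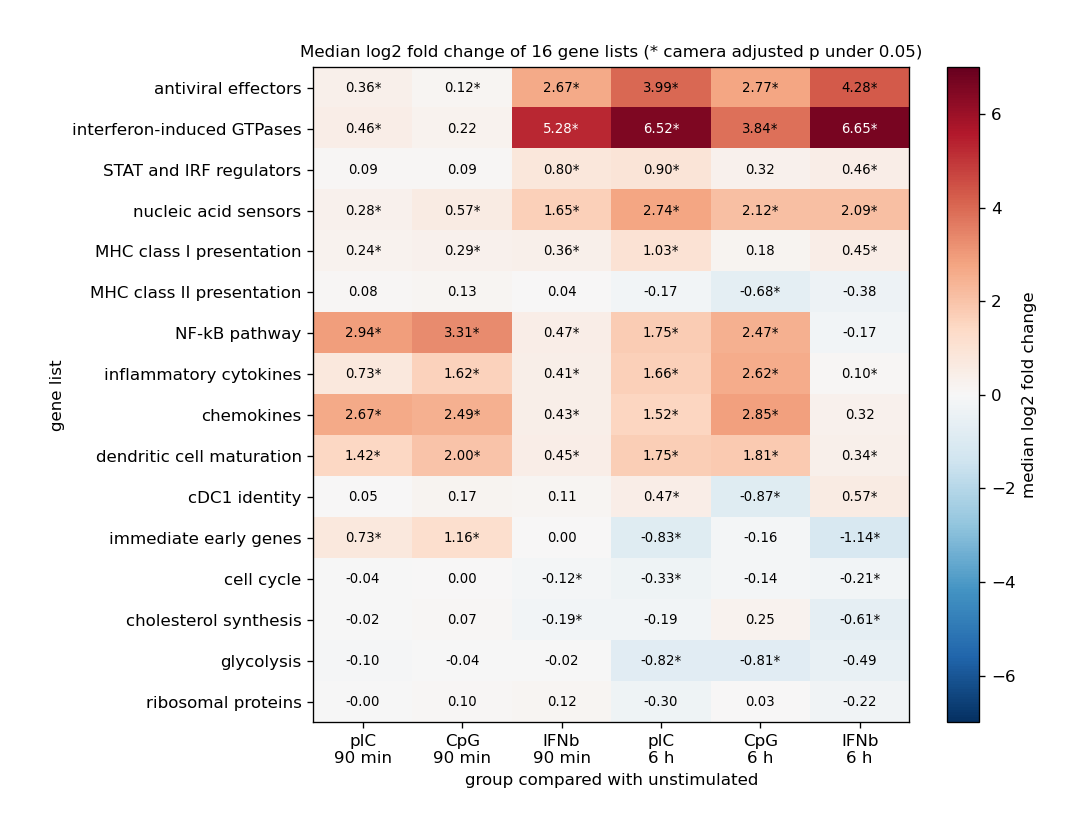
Median log2 fold change against unstimulated cells of 16 gene lists (colour and number), with genes at their bounds, for 3 stimuli at 2 times and 3 libraries per group, with an asterisk where the camera adjusted p was under 0.05. Antiviral effectors had a median of 0.36 with pIC at 90 min and 3.99 at 6 h.

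The next comparisons asked how the stimuli differed from each other at one time, directly and without the unstimulated libraries in the contrast. At 90 min, pIC and IFNb differed in 4719 genes, 2479 higher and 2240 lower with pIC, 909 and 825 of them at least 2-fold. Il12b was higher with pIC by 8.46 ± 0.23 (adjusted p = 3.27e-13), Tnf by 7.28 ± 0.18, Ccl5 by 7.47 ± 0.27, Nfkbia, the feedback inhibitor of NF-κB, by 3.14 ± 0.08, and Ifnb1 by 7.89 ± 0.35, with 2 of 3 IFNb libraries at the floor. Genes of interferon signalling were lower with pIC, among them Socs1 (-6.15 ± 0.27), Usp18 (-3.57 ± 0.13), Stat2 (-3.39 ± 0.11), Stat1 (-2.43 ± 0.11) and Irf9 (-1.69 ± 0.08). Among genes lower with pIC, Iigp1 (-8.74 ± 0.80) and Ifi208 (-7.03 ± 0.34) differed most, each with 2 of 3 pIC libraries at the floor. Oasl1 did not differ (0.03 ± 0.12, adjusted p = 0.911), and Isg15 differed by -1.26 ± 0.21. Irf8 was lower with pIC, at -1.76 ± 0.09.

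Antiviral effectors were lower with pIC in 58 of 64 genes and higher in 1 (59 and 1 adjusted over the list alone), with a median of -2.23 (camera adjusted p = 1.48e-47). GTPases were lower in 18 of 21 (4.13e-22) and nucleic acid sensors in 19 of 29, with 6 higher (2.73e-13). NF-κB pathway genes were higher in 29 of 32 (31 adjusted over the list alone, median 2.67, 3.12e-40), and maturation genes, interferon genes and the unfolded protein response moved the same way and held, while STAT and IRF regulators were lower with pIC. Inflammatory cytokines (0.0675), chemokines (0.0508), immediate early genes (0.0508), cell cycle genes (0.133) and cholesterol synthesis (0.699), all higher with pIC, lost their call with an estimated correlation. With the 2 groups fitted alone 2031 genes were called, and quantile normalization moved the share of higher calls from 52.5% to 48.9%.

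CpG and IFNb differed at 90 min in 5555 genes, 2715 higher and 2840 lower with CpG, 899 and 1044 of them at least 2-fold. Il12b (10.89 ± 0.23, adjusted p = 1.19e-14), Cxcl2 (8.48 ± 0.36), Il1b (8.35 ± 0.46) and Tnf (8.22 ± 0.18) were higher with CpG, and Cxcl1 was at least 35.8-fold higher than in IFNb libraries at the floor. Il23a, a partner of the Il12b product, differed by 6.30 ± 0.50. Ifi208 was at least 67.4-fold lower with CpG, whose 3 libraries were at the floor for it. Ifit1 (-5.96 ± 0.49), Isg15 (-4.30 ± 0.21), Stat2 (-3.74 ± 0.11), Oasl1 (-2.06 ± 0.12) and Socs1 (-5.99 ± 0.27) were lower with CpG. Irf8 differed by -2.23 ± 0.09 and Cd40 by 1.86 ± 0.10.

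All 32 NF-κB pathway genes were higher with CpG, with a median of 3.10 (camera adjusted p = 3.48e-43), and antiviral effectors were lower in 59 of 64 and higher in 2 (60 and 3 adjusted over the list alone, median -2.44, 8.69e-44). GTPases were lower in 19 of 21 (3.23e-18), nucleic acid sensors in 20 of 29 with 5 higher (2.62e-12), and STAT and IRF regulators in 10 of 17 with 4 higher (0.000257). Maturation genes (19 higher and 6 lower of 31, 22 and 6 adjusted over the list alone, 6.77e-10), immediate early genes, chemokines and the unfolded protein response were higher with CpG, as were inflammatory cytokines, whose median of 0.70 became 0.30 with genes at their bounds. Cell cycle genes (0.165) and cholesterol synthesis (0.679) lost their call with an estimated correlation. With the 2 groups fitted alone 3282 genes were called, and quantile normalization moved the share of higher calls from 48.9% to 52.7%.

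pIC and CpG differed at 90 min in 717 genes, 416 higher and 301 lower with pIC, 196 and 57 of them at least 2-fold. At the floor were 2135, 3726 and 2368 genes in pIC replicates 1, 2 and 3, and 3611, 3807 and 3879 in CpG replicates 1, 2 and 3. Part of the excess of higher calls with pIC may come from this, which was not tested. The genes of type III and type I interferons were higher with pIC: Ifnl2 was at least 11.7-fold higher than in CpG libraries at the floor, Ifnl3 differed by 4.23 ± 0.19 with 2 of 3 CpG libraries at the floor, and Ifnb1 by 2.61 ± 0.35 (adjusted p = 0.000321). Isg15 (3.05 ± 0.21), Ifit1 (3.32 ± 0.49) and Acod1 (2.11 ± 0.27) were higher with pIC as well. Nfkbiz, a cofactor of NF-κB for secondary genes, differed by -2.75 ± 0.20, Il12b by -2.42 ± 0.23 and Ccl3 by -2.28 ± 0.22. Stat1 (0.15 ± 0.11), Nfkbia (0.08 ± 0.08), Junb (-0.10 ± 0.11) and Socs1 (-0.16 ± 0.27) did not differ; quantile normalization called Junb at -0.60. With the 2 groups fitted alone 40 of 58 calls of named genes ended, among them Tnf (-0.94 ± 0.18), Cd40 (-0.59 ± 0.10), Mx1 (-1.11 ± 0.16) and Irf8 (0.47 ± 0.09), and all 58 ended with the replicate block added.

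Interferon genes were higher with pIC in 3 of 5 (camera adjusted p = 8.11e-09). NF-κB pathway genes were lower in 10 of 32 (1 up and 21 down adjusted over the list alone, median -0.42, 1.84e-19), maturation genes in 7 of 31 (17 adjusted over the list alone, 2.11e-10) and inflammatory cytokines in 7 of 27 with 1 higher (2 and 9 adjusted over the list alone, 0.000273). Of 12 lists called, 8 lost their call with an estimated correlation: antiviral effectors, with 13 of 64 higher and 2 lower (18 and 6 adjusted over the list alone, 0.147), and stromal markers (0.533), both up, and immediate early genes (0.136), MHC class I presentation (0.428), glycolysis (0.533), oxidative phosphorylation (0.648), ribosomal proteins (0.682) and reference genes (0.402), all down. The last 4 of these lists had 0 called members in limma; their medians lay between -0.12 and -0.07, and camera compares a list with all other genes. This comparison moved most with the settings: 33 genes were called with the 2 groups alone and 466 without CpG 90 min replicate 1, and quantile normalization moved the share of higher calls from 58.0% to 29.9%.

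At 6 h, pIC and IFNb differed in 3644 genes, 1648 higher and 1996 lower with pIC, 658 and 321 of them at least 2-fold. Cxcl10 was higher with pIC by 2.14 ± 0.16. Isg15 (-0.28 ± 0.21), Ifit1 (0.57 ± 0.49), Irf7 (-1.19 ± 0.50), Stat1 (-0.26 ± 0.11) and Irf9 (-0.12 ± 0.08) did not pass, although all of them were called when the 2 groups were fitted alone. Ccl5 was higher with pIC by 8.42 ± 0.27 (adjusted p = 4.37e-12), Ccl22 by 7.42 ± 0.31, Il12b by 5.50 ± 0.23 with 2 of 3 IFNb libraries at the floor and the third just above it, Ccr7 by 4.47 ± 0.34 with 1 at the floor, Tnf by 3.81 ± 0.18 and Cd8a, the lineage marker of these cells, by 2.74 ± 0.08. Lower with pIC were P2ry12, a purine receptor gene (-2.67 ± 0.20), Il10, an anti-inflammatory cytokine gene (-2.62 ± 0.26), and Socs1 (-1.23 ± 0.27). Stat2 (-0.51 ± 0.11) and Irf8 (-0.46 ± 0.09) were lower with pIC but lost their call with quantile normalization.

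NF-κB pathway genes were higher with pIC in 26 of 32 and lower in 1 (28 and 1 adjusted over the list alone, median 1.68, camera adjusted p = 1.35e-36), and maturation genes, chemokines and inflammatory cytokines moved the same way. Glycolysis was lower in 11 of 20 (14 adjusted over the list alone, 1.49e-08), cDC1 identity in 18 of 32 with 5 higher (1.69e-05, 0.0464 with an estimated correlation) and the unfolded protein response in 12 of 21 with 2 higher (0.000272). Of 17 lists called, 10 lost their call with an estimated correlation. Antiviral effectors, with 3 higher and 16 lower of 64 (0.487), nucleic acid sensors (0.098), cell cycle genes (0.125) and oxidative phosphorylation (0.593) were lower with pIC, and cholesterol synthesis (0.129), cell death (0.0539), MHC class I presentation (0.487), negative regulators (0.35), macrophage markers (0.487) and immediate early genes (0.543, median -0.01 and mean 0.43) were higher. With library quality weights 6225 genes were called.

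CpG and IFNb differed at 6 h in 8015 genes, 3785 higher and 4230 lower with CpG, 1496 and 2013 of them at least 2-fold. Il1b (13.19 ± 0.46, adjusted p = 1.11e-12), Il12b (13.01 ± 0.23, with 2 of 3 IFNb libraries at the floor and the third just above it), Ccl3 (11.31 ± 0.22) and Ccr7 (8.82 ± 0.34, with 1 at the floor) were higher with CpG. Iigp1 (-6.97 ± 0.80), Acss1 (-6.80 ± 0.31), Irf7 (-5.31 ± 0.50), Tlr11 (-4.77 ± 0.12), Tlr3 (-4.23 ± 0.15) and Irf8 (-3.50 ± 0.09) were lower with CpG. Isg15 differed by -2.06 ± 0.21 and Stat1 by -1.51 ± 0.11, while Irf9 (-0.07 ± 0.08) and Cxcl10 (-0.18 ± 0.16) did not pass.

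NF-κB pathway genes were higher with CpG in 30 of 32, with a median of 2.51 (camera adjusted p = 9.13e-26). Antiviral effectors were lower in 59 of 64 and higher in 3, with a median of -1.59 (4.95e-21), cDC1 identity was lower in 24 of 32 and higher in 6 (1.85e-09, 0.00924 with an estimated correlation), and nucleic acid sensors in 21 of 29 with 3 higher (7.17e-09). STAT and IRF regulators were lower, and maturation genes and inflammatory cytokines, whose median of 1.69 became 0.51 with genes at their bounds, were higher. Of 16 lists called, 9 lost their call with an estimated correlation: cholesterol synthesis (0.124), negative regulators (0.103), chemokines (0.0783), immediate early genes (0.238) and macrophage markers (0.342), all higher with CpG, and GTPases (0.124), MHC class I (0.103) and class II presentation (0.124) and glycolysis (0.103), all lower.

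pIC and CpG differed at 6 h in 6406 genes, 3418 higher and 2988 lower with pIC, 1581 and 822 of them at least 2-fold. Ccl3 (-10.44 ± 0.22, adjusted p = 5.98e-14), Ccl4 (-8.23 ± 0.30), Il12b (-7.51 ± 0.23), Il1b (-7.43 ± 0.46), Nos2 (-7.23 ± 0.30) and Il6 (-5.34 ± 0.18) were lower with pIC. Iigp1 (5.09 ± 0.80), Il12rb1, a receptor subunit for the Il12b product (4.70 ± 0.37), Irf7 (4.12 ± 0.50), Irf8 (3.04 ± 0.09), Cxcl10 (2.31 ± 0.16) and Stat2 (1.75 ± 0.11) were higher. Ccr7 differed by -4.35 ± 0.34, a value that quantile normalization put at -2.70. Ifnb1 (-0.59 ± 0.35), Socs1 (0.38 ± 0.27) and Irf9 (-0.05 ± 0.08) did not pass; Socs1 was called with the 2 groups fitted alone.

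Antiviral effectors were higher with pIC in 59 of 64 and lower in 3 (60 and 3 adjusted over the list alone), with a median of 1.30 (camera adjusted p = 1.38e-25). GTPases (20 of 21, 1.13e-10), cDC1 identity (23 higher and 4 lower of 32, 1.33e-11), nucleic acid sensors (20 higher and 4 lower of 29, 1.13e-10), MHC class I (20 of 26, 1.13e-10) and class II presentation (11 higher and 1 lower of 17, 4.08e-06), STAT and IRF regulators and cell death genes were higher as well. NF-κB pathway genes were lower in 25 of 32 and higher in 4 (26 and 5 adjusted over the list alone, 1.13e-10), as were inflammatory cytokines and the unfolded protein response. Of 18 lists called, 7 lost their call with an estimated correlation, all lower with pIC: negative regulators (0.162), chemokines (0.25), immediate early genes (0.26), cell cycle genes (0.162), cholesterol synthesis (0.285), macrophage markers (0.464) and ribosomal proteins (0.657). Quantile normalization left 2263 genes higher and 2612 lower with pIC, which moved the share of higher calls from 53.4% to 46.4%.

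The comparisons of 6 h with 90 min within 1 stimulus asked what changed with time. They set the 2 sets of libraries against each other that differed in haemoglobin and collagen transcripts, and no unstimulated library was taken at 6 h. With pIC, 10130 genes changed, 4790 up and 5340 down, 2144 and 2027 of them at least 2-fold. Stat1 rose by 4.31 ± 0.11 (adjusted p = 7.45e-14), Stat2 by 3.42 ± 0.11, Usp18 by 4.73 ± 0.13, Ifit3 by 8.39 ± 0.60, and Irf7, which drives the later interferon genes, by 7.76 ± 0.50 with 1 of 3 libraries of 90 min at the floor. Ifi208 rose by 8.51 ± 0.34 with 2 of 3 libraries of 90 min at the floor. Ifnb1 fell by 5.27 ± 0.35, Il12b fell by 4.33 ± 0.23, Tnf fell by 4.28 ± 0.18 and Chac1, a stress-induced gene of glutathione breakdown, fell by 5.89 ± 0.20. Egr4 fell by 8.28 ± 0.46 with 2 of 3 libraries of 6 h at the floor, and Ifnl3 was at least 7.1-fold lower. Irf8 rose by 1.89 ± 0.09.

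All 64 antiviral effectors rose from 90 min to 6 h with pIC, with a median of 3.13 (camera adjusted p = 2.5e-44). GTPases rose in 20 of 21 (4.48e-17), their median of 5.73 becoming 4.87 with genes at their bounds, and nucleic acid sensors in 21 of 29 with 5 down (1.27e-09). STAT and IRF regulators rose in 10 of 17 and fell in 4 (0.00198). Immediate early genes fell in 27 of 33 and rose in 3 (3.31e-13), NF-κB pathway genes fell in 25 of 32 and rose in 1 (26 and 2 adjusted over the list alone, 1.09e-09), cell cycle genes fell in 27 of 40 and rose in 6 (28 and 6 adjusted over the list alone, 0.000222), and interferon genes fell in 3 of 5. The rise of cDC1 identity (0.217) and the fall of glycolysis (0.162) lost their call with an estimated correlation.

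With CpG, 9909 genes changed from 90 min to 6 h, 5048 up and 4861 down, 2256 and 2126 of them at least 2-fold. Nos2, the inducible nitric oxide synthase, rose at least 205-fold and Cxcl13, a B cell chemokine gene, at least 83.3-fold above libraries of 90 min at the floor. Ifit1 rose by 5.93 ± 0.49, Isg15 by 4.39 ± 0.21 (adjusted p = 6.83e-11), Usp18 by 3.78 ± 0.13 and Stat1 by 3.20 ± 0.11. Egr3 fell by 6.76 ± 0.21, Fosb fell by 5.68 ± 0.26, Cxcl10 fell by 3.10 ± 0.16 and Irf1 fell by 2.74 ± 0.12. The class II loading gene H2-DMa fell by 3.53 ± 0.16, and Tlr12, a gene of cDC1 cells, fell by 3.45 ± 0.08. Several values moved with quantile normalization of the centred values. Ccr7 went from 6.13 ± 0.34 to 4.02, Il6 from 4.02 ± 0.18 to 2.33 and Ccl3 from 5.86 ± 0.22 to 3.37. Tnf went from -1.44 ± 0.18 to -2.54. The same setting turned Il12b from 0.76 ± 0.23 to -1.31 and ended the call of Irf8, from -0.68 ± 0.09 to 0.03.

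Antiviral effectors rose from 90 min to 6 h with CpG in 56 of 64 and fell in 1 (56 and 2 adjusted over the list alone), with a median of 2.35 (camera adjusted p = 7.66e-26, 0.00196 with an estimated correlation). Of the 9 lists called, the other 8 lost their call with an estimated correlation. Rises were lost for GTPases, up in 19 of 21 (0.0555), and nucleic acid sensors, up in 18 and down in 8 of 29 (0.0899). Falls were lost for immediate early genes, down in 29 of 33 and up in 1 (0.0522), glycolysis, down in 18 of 20 (0.0555), NF-κB pathway genes (0.0555), MHC class I (0.277) and class II presentation (0.0693) and cDC1 identity (0.0758). Quantile normalization moved the share of higher calls from 50.9% to 49.7%.

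With IFNb, 8829 genes changed from 90 min to 6 h, 4481 up and 4348 down, 1473 and 1368 of them at least 2-fold. Ifi44 rose by 5.05 ± 0.36, Irf7 by 5.04 ± 0.50, Isg15 by 2.14 ± 0.21, Stat1 by 2.14 ± 0.11 (adjusted p = 1.06e-09) and Xcr1, the chemokine receptor of cDC1 cells, by 1.73 ± 0.07. Cxcl13 rose by 6.40 ± 0.20 with 2 of 3 libraries of 90 min at the floor. Cish, an early feedback inhibitor of STAT signalling, fell by 5.88 ± 0.36, Socs1 fell by 2.81 ± 0.27, Junb fell by 2.07 ± 0.11 and Cd40 fell by 1.25 ± 0.10. Hist1h2ak fell by 7.44 ± 0.70, and Gas6 was at least 16-fold lower. Ifnb1 (0.27 ± 0.35) and Il6 (-0.16 ± 0.18) did not pass. Calls for Stat2 (0.54 ± 0.11) and Tnf (-0.80 ± 0.18) ended both with quantile normalization and with the 2 groups fitted alone, and the call of Pacsin1, higher at 6 h, ended with quantile normalization, at -0.23.

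Antiviral effectors rose from 90 min to 6 h with IFNb in 58 of 64 (59 up and 1 down adjusted over the list alone), with a median of 1.33 (camera adjusted p = 1.74e-23). With an estimated correlation, cDC1 identity, up in 20 and down in 4 of 32, nucleic acid sensors, up in 20 and down in 4 of 29, and immediate early genes, down in 26 and up in 2 of 33, each held at 0.0493. Rises of MHC class I presentation (0.537) and GTPases (0.537) lost their call, as did falls of NF-κB pathway genes (0.072), cholesterol synthesis (0.537), glycolysis (0.531), macrophage markers (0.583) and ribosomal proteins (0.864).

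The last comparisons asked in which of 25 panel genes the change from 90 min to 6 h differed between stimuli, and 63 of 75 tests were called. For pIC against IFNb 23 genes differed. The change of Ifnb1 differed by -5.54 ± 0.49 (adjusted p = 2.79e-08), that of Tnf by -3.47 ± 0.25, and those of Socs1 (4.92 ± 0.39), Usp18 (3.09 ± 0.19) and Stat2 (2.88 ± 0.16) in the other direction. Usp18 and Stat2 gained more from 90 min to 6 h with pIC than with IFNb, and Socs1 fell with IFNb. Cxcl10 (-0.04 ± 0.22) and Junb (-0.24 ± 0.16) did not pass. For CpG against IFNb 20 genes differed, led by Ccr7, a homing receptor gene of mature cells, at 5.75 ± 0.49 (adjusted p = 1.97e-08), Socs1 at 4.39 ± 0.39, Il6 at 4.18 ± 0.25 and Ifit1 at 3.88 ± 0.69. Oasl1, Rel, Rsad2, Nfkbia and Tap1 did not pass. For pIC against CpG 20 genes differed: Il12b by -5.09 ± 0.33 (adjusted p = 6.83e-10) and Il6 by -5.06 ± 0.25, against Irf7 by 4.40 ± 0.70 and Irf8 by 2.57 ± 0.13. Cd40, Oasl1, Socs1, Ifit1 and Xcr1 did not pass. Among all tested genes 3372, 5992 and 4270 differed for the 3 pairs.

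Genes called higher than in unstimulated cells with all 3 stimuli numbered 437 at 90 min, against 21.5 for independent calls, and 2725 at 6 h, against 278. Of the genes higher with IFNb, 33.4% at 90 min and 81.4% at 6 h were also higher with pIC, and 33.0% and 63.3% with CpG. pIC and CpG shared 1701 higher genes at 90 min, against 290 for independent calls, and 3563 at 6 h, against 1252. Genes lower with all 3 numbered 582 at 90 min and 2656 at 6 h. All of these comparisons used the same 3 unstimulated libraries, which could not be divided between them, so part of each overlap may come from the shared controls. The 6 h groups also share their time in culture and the set of libraries that differed in haemoglobin and collagen transcripts. Part of the larger overlap at 6 h may come from these. Of 20507 genes, those higher with pIC numbered 2331 at 90 min and 4958 at 6 h, and those higher with CpG 2551 and 5180. At 90 min the log2 fold changes of pIC and IFNb had a covariance of 0.142 and a correlation of 0.307, those of CpG and IFNb 0.126 and 0.261, and those of pIC and CpG 0.435 and 0.786; at 6 h these were 0.967 and 0.837, 0.696 and 0.537, and 1.02 and 0.739. In 20 simulated sets of libraries without any effect the shared controls alone gave covariances of 0.059 to 0.060 and correlations of 0.496 to 0.504. With equal spread and equal group sizes, the simulated correlations were fixed by the design. They are no measure for correlations of real changes, whose variance also holds the effects. Only the covariances can be set beside each other, and each observed one was larger than the simulated ones.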

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

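The test of sequencing depth below and the counts of other splits of the libraries were chosen only after the results they concern had been seen. The change from 90 min to 6 h differed between stimuli, by a test of the difference itself, in 23 of 25 panel genes for pIC against IFNb, in 20 for CpG against IFNb and in 20 for pIC against CpG. The largest differences of the 3 pairs were those of Ifnb1 (-5.54, SE 0.49, adjusted p = 2.79e-08), Ccr7 (5.75, SE 0.49, adjusted p = 1.97e-08) and Il12b (-5.09, SE 0.33, adjusted p = 6.83e-10). Among all tested genes the change with time differed in 3372 genes for pIC against IFNb, 5992 for CpG against IFNb and 4270 for pIC against CpG. Each of these differences uses libraries of 90 min and of 6 h, which also differ in the transcripts described next. A shift of equal log2 size for both stimuli cancels in such a difference. One that varies between the groups does not.

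Haemoglobin and collagen transcripts stood far above their lowest value in the unstimulated and 90 min libraries and near the floor in the 6 h libraries. A lower depth of the 6 h libraries is argued against, since with 3 reads per library in place of the floor the median least fall of the 5 transcripts was still 2.51 (log2). RNA of another tissue in the earlier libraries is a candidate source that cannot be told apart from the groups: 3 of 5 tissue lists with at least 5 tested members were lower at 6 h than at 90 min by a median of at least 0.5, namely skeletal muscle (-1.48, 10 of 10 lower), fat (-2.11, 8 of 8) and connective tissue (-1.36, 10 of 13), while heart (0.22) and brain (0.23) were not, with some members near the floor at both times (libraries at the floor of 9 at 90 min and of 9 at 6 h: Myh6 8 and 7, Syt1 7 and 8, Camk2a 8 and 7). Heights above the lowest value of each gene at 90 min and at 6 h were, for heart and brain members at the floor in 0 libraries, 1.46 and 1.43 (Tnni3), 1.36 and 2.22 (Mybpc3), 1.17 and 1.40 (Mbp), 1.04 and 2.32 (Plp1) and 3.38 and 1.14 (Slc17a7), and in the lists that were lower 5.46 and 1.64 for Car3, 4.18 and 0.88 for Sparc and 3.94 and 0.15 for Myh4, and the smaller lists gave 0.01 for liver, -0.22 for skin, -0.86 for red cells, 0.07 for pancreas and gut, -0.38 for kidney and -0.09 for lung. A fall with time in stimulated cells (median -4.06 at 6 h against unstimulated for the 5 transcripts) also stays open, because no unstimulated library was taken at 6 h and the labels give no batch.

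In IFNb 90 min replicate 2 the induction of 248 of 357 genes was weaker than in the other replicates, at a median share of 0.838 (quartiles 0.627 and 1.06). The genes were chosen by their induction in the other replicates, which itself favours a lower value in the left-out library. No matching count was made with another replicate left out. A mixture with RNA of unstimulated cells was examined as a source of the weaker induction. Of the genes steady between unstimulated cells and the other replicates, 2.99% deviated at least 2-fold in this library. The other replicates had 1.10% and 0.919%, and the ratio to the higher of these was 2.71. The prediction for a mixture allowed no more deviating genes than in the other replicates, so this part of it failed. The interquartile range of the shares, 0.437, was wider than that prediction allowed, while the median share lay within it. Both the range and the ratio also fell short of the values set beforehand against a mixture, so the test did not decide and a mixture stays open. RNA of another tissue is a further candidate source: 3 of 5 tissue lists were higher in this library by a median of at least 0.5, skeletal muscle (1.02), fat (2.49) and connective tissue (1.94), against 0 for heart and brain, where some members were at the floor and Tnni3 stood at 1.70 against 1.39 in the other replicates and Mbp at 0.00 against 0.23. Above its lowest value Car3 stood at 7.32 in this library and 4.89 in the other replicates, Sparc at 6.01 and 3.57, and Myh4 at 5.97 and 2.94, but the library was not alone in this: unstimulated replicate 2 was the highest of its group for all 5 haemoglobin and collagen transcripts (Col1a1 2.46 against 0.75 and 0.98 as deposited) and pIC 90 min replicate 2 for 4 of them (Col1a1 2.36 against 0.89 and 1.19). No biological explanation was tested, since the design names none for a single replicate.

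For each count of changed genes, 6 libraries in 2 groups of 3 make 10 splits, too few for a share under 0.05, and 1 of the 10 splits, the real one, gave a count as large in each comparison. Every other split mixes libraries of the 2 real groups, so a real difference widens the spread and lowers its count. The counts of other splits are therefore no estimate of false calls. Against unstimulated cells the real count and the highest of the other splits were 4252 and 19 (pIC), 5106 and 3 (CpG) and 2826 and 27 (IFNb) at 90 min, and 9567 and 2, 10060 and 1, and 8985 and 1 at 6 h. Between stimuli they were 4719 and 129 (pIC against IFNb), 5555 and 17 (CpG against IFNb) and 717 and 30 (pIC against CpG) at 90 min, and 3644 and 9, 8015 and 5, and 6406 and 7 at 6 h. From 90 min to 6 h they were 10130 and 24 (pIC), 9909 and 3 (CpG) and 8829 and 4 (IFNb).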

How the results depend on the processing

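The library quality weights, the fit without 3 doubted libraries and the replicate block with only the 2 groups compared were chosen after seeing the data. Of 1678 calls of named genes, those lost numbered 63 with quantile normalization, 10 without the trend and robust options of limma, 15 with no filter on low values, 10 with the replicate block, 17 with library quality weights, 32 without the 3 doubted libraries and 118 in at least 1 fit that left out a library, and 0 of 1653 with the stricter filter. With only the 2 groups compared 152 of 1669 were lost, and 437 of 1678 with the replicate block added to that. These fits use 6 libraries in place of 21 and take their spread from the compared groups alone. Without the block, losses were 24 of 98 for IFNb 90 min against unstimulated and 40 of 58 for pIC against CpG at 90 min. For pIC 6 h against unstimulated they were 1 of 124. Counts of changed genes in both directions together stayed within 1.5 times under quantile normalization, both filters and the replicate block over all libraries. The floor limits folds of genes absent from a group to bounds. The pseudocount alternative was not run, because the deposited values are already log values.

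With an estimated correlation 120 of 200 gene list tests were called. No called list turned its direction in the other settings that were run over all comparisons, which for the stricter filter held 435 of 465 tests. The lists were not tested with only the 2 groups compared. With the block added to that, they were tested for IFNb 90 min against unstimulated alone. With only the 2 groups compared the counts were 2611 (pIC) and 1093 (IFNb) at 90 min against unstimulated, 2031 for pIC against IFNb, 3282 for CpG against IFNb and 33 for pIC against CpG at 90 min. With the replicate block and only the 2 groups compared they were 286 (pIC), 2054 (CpG) and 450 (IFNb) at 90 min against unstimulated, 345 for pIC against IFNb, 1964 for CpG against IFNb and 2586 for IFNb at 6 h against 90 min; for pIC against CpG at 90 min limma called 0 genes, with 2465 at an unadjusted p under 0.05. Library quality weights gave 6225 genes for pIC against IFNb at 6 h. The main fit used the same spread of a gene for all 7 groups. It can understate the error of a group with a wide spread and overstate that of a narrow one. The median SD over genes was 0.081 in both the pIC 6 h and the IFNb 6 h group. It was 0.222 in the IFNb 90 min group and 0.150 in the unstimulated group. The cause of the higher count was not tested. Quantile normalization, run on centred values, turned 8 named values. Against unstimulated, Usp18 went to -0.70 and Mx1 to -0.35 (pIC at 90 min), and Isg15 to -0.0526 (CpG at 90 min). Tnf went to -0.47 (IFNb at 90 min) and -0.66 (IFNb at 6 h), also against unstimulated. For 6 h against 90 min, Irf8 went to 0.0259 and Il12b to -1.31 (CpG), and Pacsin1 to -0.23 (IFNb). The cause was not tested, and making the distributions of centred values equal can itself move such values.

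Leaving out each library in turn gave, at 90 min against unstimulated, 3513 to 3923 (pIC), 4202 to 4687 (CpG) and 2236 to 2813 genes (IFNb), and at 6 h 8734 to 9074, 9305 to 9528 and 8103 to 8407. Between stimuli it gave 4061 to 5080 (pIC against IFNb), 4630 to 5951 (CpG against IFNb) and 466 (without CpG 90 min replicate 1) to 843 (pIC against CpG) at 90 min, and 2850 to 2979, 7213 to 7438 and 5607 to 5845 at 6 h. From 90 min to 6 h it gave 9062 to 9764 (pIC), 9163 to 9393 (CpG) and 7778 to 8960 (IFNb). Panel tests called ranged from 59 to 64, shared genes from 362 to 532 at 90 min and from 2403 to 2973 at 6 h, and gene list tests from 194 to 209.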

Other observations

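Genes for the proteins whose binding was profiled in other samples of the series formed a list of 12, which IFNb at 90 min raised in 4 (camera adjusted p = 0.000121, 0.00804 with an estimated correlation), with a median of 0.27. With pIC at 6 h 5 rose and 2 fell (adjusted p = 0.0193), a call lost with an estimated correlation (adjusted p = 0.0783), and with CpG at 6 h 7 rose and 2 fell without a call for the list (adjusted p = 0.108). Cholesterol synthesis fell with IFNb at 6 h against unstimulated cells in 20 of 24 genes and rose in 1, with a median of -0.61 (2.24e-06), a call lost with an estimated correlation (adjusted p = 0.26). No neutrophil marker of 7 passed at 6 h with any stimulus. Of the 647 genes in any list, 37 were in at least 2.

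A rise of interferon-induced genes late after CpG was noticed and then tested on the same data, so it stands as a hypothesis. Of 743 genes that IFNb raised at least 2-fold at 90 min, 397 (53.4%) were higher with CpG at 6 h than at 90 min and 122 lower, against 23.5% higher of 19764 other genes, a ratio of 2.27 (1.90 without genes at the floor). A delayed response to interferon after CpG may account for this; the 6 h and 90 min libraries also differ in the transcripts of other tissues, and no library without interferon signalling was in the table.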
